A study of Mus musculus with 12 samples.

How the data were processed

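RNA was measured on 12 Illumina MouseRef-8 bead arrays, 1 per mouse, from the cerebellum of C57BL/6 mice, per the labels. The design crossed genotype (wild type, WT, or CX, which lacks both Csa and Xpa) with treatment (nicotinamide riboside, NR, or saline), with 3 mice in each of the 4 groups. NR was injected under the skin at 500 mg per kg body weight per day for 14 days in mice of 3 months, and tissue was taken on day 15, per the labels' protocols. Total RNA was extracted with TRIzol and biotin-labelled cRNA was hybridised overnight, per the labels' protocols. The program BeadStudio 1.9.0 is named in the submitters' processing notes; further settings are not given in the sources used here.

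The deposited signal table holds an intensity for each of 25697 probes on each array, on a linear scale from 27.9 to 37300.2, with no normalization between arrays. Its signal columns are headed as z-scores, but their values are linear intensities. The same table holds, per the file headers, a detection p-value for each probe on each array; the reference distribution behind it is not given in the sources used here. The deposited series matrix holds a score per probe: the log10 intensity minus the array mean, divided by the array SD, as a recomputation from the signal table showed to within 5e-10. Its column medians ran from -0.486 to -0.437. Every matrix column matched 1 signal column of its own group. The signal columns carry no replicate number, so the arrays of a group are called A, B and C in the order of the table.

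Probes were named from the platform annotation supplied with the data and a gene table of the mouse assembly GRCm38.p6, used for names and gene order only. Of the 25697 probes, 23978 had 1 gene symbol, 0 had several, and 1719 were not listed and stay unnamed. Entrez identifiers of 23962 probes matched the gene table.

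Signals were processed in R 4.3.3 with limma 3.58.1 and its function neqc. Background was corrected by a normal-exponential model whose background mean and SD came from the detection p-values, because no negative control probes were in the files used here. An offset of 16 was added, arrays were quantile normalized, and values were taken to log2. A probe was kept when its detection p-value was under 0.05 on at least 3 arrays, which left 15725 probes (61.2%), of which 14817 carried a symbol of 10631 genes. A model with 4 group means was fitted to all 12 arrays with lmFit, so that the groups shared one estimate of the spread. The 5 contrasts were genotype under saline, genotype under NR, NR in CX, NR in WT, and the NR by genotype interaction (NR effect in CX minus NR effect in WT). Tests used eBayes with a trend, were two-sided, and were adjusted by the Benjamini-Hochberg method over all probes of a comparison. A probe was called at an adjusted p under 0.05. All adjusted p-values of single genes are from this limma fit, and errors of log2 fold changes are its standard errors. Where a probe was detected on no array of the dimmer group, the fold is given as a lower bound against the higher of the probe's own signal and the lowest detected signal there.

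Gene lists were written before the data were examined: 33 lists of pathways and cell types, of which 6 cover the study's question (nucleotide excision repair, p53 targets, PARPs and base excision repair, NAD metabolism, sirtuins and mitochondrial biogenesis, and mitophagy and mitochondrial dynamics). Each gene entered a list test with its kept probe of highest mean. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 33 lists within a comparison. They were tested again with a correlation estimated per list, and with fry, which asks whether a list's genes move one way on balance without comparing them with other genes. Some lists share genes: the interferon and reactive astrocyte lists share 3, and the microglia and lysosome lists share 2. Many markers of microglia, astrocytes and vessels are also expressed in other cells.

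The rule for named genes was set before the data were examined, as were the design, the threshold and the alternatives, except those named below. For genotype under saline, NR in CX and NR in WT, it took the 6 highest and 6 lowest log2 fold changes among called probes. Where fewer were called, the smallest unadjusted p in that direction filled the places. It also took the 3 members with the smallest p of each list called in that comparison, in the list's direction, and the 2 with the smallest p of each study list. For genotype under NR and the interaction it took the 5 highest and 5 lowest. Ercc8 (the gene symbol of Csa) and Xpa were reported on every array, and Parp1, Sirt1, Ppargc1a, Nampt, Nmrk1 and Pink1 in each comparison. Ucp2 was on the same list, but no annotated probe carries its symbol. Of several probes of a gene, the one with the smallest p in the comparison is given, and it is stated where another differs in call or sign. Genes named outside the rule were chosen after their values were seen.

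Alternatives covered the background correction, the normalization (array medians set equal, or z-scores), the series matrix values, the detection filter (none, or detection p under 0.01 on all 12 arrays), the arrays in the fit, array weights, the variance trend, the replicate number as a block, 1 probe per gene, and each array left out in turn. The z-scores and the series matrix values are the same scores put on one scale. These settings therefore repeat each other and are not separate alternatives, although counts of settings hold both. A slide block was not fitted because the files used here give no slide. Array brightness (the log2 median signal) as a covariate, the signal of the Y-linked gene Eif2s3y as a covariate, and the fit without the 3 arrays that carry it were added after seeing the data. That last fit leaves only array C of WT saline. For comparisons that use WT saline, calls lost in it can come from the lost arrays alone.

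The fit was tested on simulated data drawn from each probe's real mean and residual spread, for genotype under saline, with 200 of 15725 probes changed. It recovered 21 of 67 probes changed by 1.5-fold (31.3%), 60 of 67 changed by 2-fold (89.6%) and 65 of 66 changed by 4-fold (98.5%), with 16 false calls. In a separate simulated data set in which 1 list was raised, that list was the 1 list called of 33. Probes were drawn independently in these simulations, so correlation between the genes of a list was left out. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.18 for a comparison of groups and 0.25 for the interaction. Chance values for correlations between comparisons came from 100 simulated data sets without effects and from 100 regroupings of the model's residuals.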

Results

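Gene expression was measured in the cerebellum of 12 mice, in 4 groups of 3: CX mice given nicotinamide riboside (CX NR), CX mice given saline (CX saline), and wild-type mice given the same treatments (WT NR, WT saline). CX mice lack Csa, which recruits repair factors to RNA polymerase stalled at DNA damage, and Xpa, which assembles the nucleotide excision repair complex at a lesion. Nicotinamide riboside is a vitamin form that cells convert to NAD+. Per its title, the study concerns failing clearance of mitochondria, activation of the DNA damage sensor PARP1 and loss of NAD+ and of the activity of the deacetylase SIRT1 in XPA deficiency. Each array detected between 13892 and 15314 probes (54.1% to 59.6%). The median raw signal was 102 ± 3.81 (mean ± SD, n = 3) in CX NR, 86.8 ± 6.06 in CX saline, 83.6 ± 9.53 in WT NR and 99.9 ± 9.65 in WT saline. Arrays of the same group correlated at r between 0.981 and 0.993 across probes. The labels name no individual animals beyond a replicate number, so adjusted p-values treat each array as 1 mouse. The signal columns carry an animal or array number, lower for every saline array than for every NR array, so treatment ran with that order. What the number counts is not given in the sources used here. The labels give all mice as male. On 9 arrays, among them all 6 CX arrays, Xist, expressed from the inactive X chromosome, was at 7.53 or above and the Y-linked gene Eif2s3y lay between 4.31 and 4.51. On WT NR array A and WT saline arrays A and B, Xist lay between 4.66 and 4.78 and Eif2s3y between 9.46 and 9.94. The values of the 9 arrays go against the male label. Every array with Eif2s3y signal was a WT array, so sex was not balanced between the genotypes.

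Xpa, and Ercc8 at 1 of its 3 probes, were lower in every CX array than in every WT array. Xpa (ILMN_2968515) had log2 signals of 8.84, 8.92 and 8.75 in CX saline and of 8.73, 8.57 and 8.69 in CX NR. In WT saline they were 9.46, 9.57 and 10.14, and in WT NR 9.98, 9.85 and 9.72. Ercc8 (the symbol of Csa) fell in this way at probe ILMN_2600315, from 7.66, 7.37 and 7.76 in WT saline to 6.60, 6.47 and 6.62 in CX saline. Its values were 7.73, 7.64 and 7.28 in WT NR and 6.84, 6.80 and 6.65 in CX NR. The log2 fold change under saline was -0.88 ± 0.16 for Xpa (SE; adjusted p = 0.00604) and -1.03 ± 0.17 for Ercc8 (adjusted p = 0.00358). Under NR it was -1.19 ± 0.16 for Xpa (adjusted p = 0.000366) and -0.78 ± 0.17 for Ercc8 (adjusted p = 0.0203). The Ercc8 call under NR ended without CX NR array B (adjusted p = 0.0774), CX NR array C (0.0983), WT NR array A (0.114) or WT NR array B (0.0817). With array brightness as a covariate, neither Xpa (adjusted p = 0.13) nor Ercc8 (0.574) was called under NR. The Ercc8 call under NR ended in 6 of the other settings, among them the fit without the 3 arrays with Eif2s3y signal (0.11). The other Ercc8 probes did not differ between genotypes past the threshold: ILMN_2719001 had 0.12 under saline and -0.45 under NR, and ILMN_2629069, detected on 3 arrays, had -0.05 and 0.21. Where these probes lie relative to the deleted exons is not given in the sources used here. NR moved neither gene past the threshold in CX (Xpa -0.17, adjusted p = 0.653; Ercc8 0.20, 0.631) or in WT (Xpa 0.13, 0.755; Ercc8 -0.05, 0.93).

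Loss of both genes in untreated mice was read from CX saline against WT saline. Sex was not matched here, since WT saline arrays A and B had Eif2s3y signal and no CX array did. Genes of immune defence and of the glial response to injury rose in the CX cerebellum, among them Lcn2, a secreted iron-binding protein of reactive astrocytes, and Fcgr4, an antibody receptor of phagocytes. Transcripts of the attracting cytokine Ccl12, of the complement component C4b and of the lectin Lgals3 rose as well. Fewer genes fell, and these included Tph2, the enzyme that makes serotonin in brainstem neurons, Gpc5, a proteoglycan of astrocytes, and the haemoglobin gene Hbb-bt. The Tph2 difference came mainly from WT saline arrays A (10.75) and C (9.42). Of 15725 probes, 322 were called: 237 higher in CX (195 genes) and 85 lower (78 genes), so 73.6% of the calls were higher. Changes over 2-fold made up 142 of the higher and 25 of the lower calls. The groups did not overlap for 3354 probes (21.3%), where chance gives 10%. The share was also 21.3% for NR in CX, where 0 probes were called, so by itself it does not mark a genotype effect. With array medians set equal in place of quantile normalization, 943 probes were called, of which 25.1% were higher, and the median of all probes lay at -0.151. The fit without the 3 arrays with Eif2s3y signal leaves only array C of WT saline, so its count is left out. The count was 203 with the strict detection filter, 207 with only the compared arrays, 822 with array weights and 113 with brightness as a covariate. It was 159 without CX saline array A, 167 without CX saline array B and 613 without CX saline array C.

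The strongest rise in CX under saline was that of Lcn2, with a log2 fold change of 5.17 ± 0.86 (adjusted p = 0.00345), or at least 32.2-fold, since no WT array detected it. It came from CX saline arrays A and B, at 11.84 and 11.43, while array C stood at 6.77 and the 6 WT arrays at 4.50 to 5.08. The Lcn2 call ended with brightness as a covariate (adjusted p = 0.0862). Without the 3 arrays with Eif2s3y signal, which leaves only array C of WT saline, its log2 fold change was 5.219. Fcgr4 rose by 3.45 ± 0.28 (adjusted p = 7.33e-06; at least 8.98-fold) and Ccl12 by 3.06 ± 0.22 (5.4e-06). The homing cytokine genes Ccl21a (2.91 ± 0.46, adjusted p = 0.00216), Ccl21b (2.84 ± 0.40, 0.00106) and Ccl21c (2.82 ± 0.34, 0.000256) rose too, but their sequences are nearly identical and these 3 probes are uncertain as separate genes. Ccl21a did not pass with brightness as a covariate (adjusted p = 0.0612).

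Microglial genes rose together in CX under saline. Of 22 measured genes of microglia and macrophages, 14 were called higher, 0 lower and 8 were not called; adjusted over the list alone, 16 were higher. Lgals3, a lectin of phagocytes, rose by 2.65 ± 0.23 (adjusted p = 1.33e-05), the lysozyme gene Lyz2 by 2.31 ± 0.22 (3.35e-05), which shares most of its sequence with Lyz1, and the complement gene C1qa by 2.17 ± 0.21 (2.75e-05). The homeostatic microglial genes P2ry12 (-0.34, adjusted p = 0.524) and Tmem119 (0.32, 0.469) were not called. The median over the list was 1.59, and camera gave an adjusted p of 1.47e-24, or 0.116 with an estimated correlation. Of 26 interferon response genes, 12 were called higher and 0 lower, or 19 adjusted over the list alone, with a median of 1.01 (adjusted p = 1.24e-21; 0.137 with an estimated correlation). Ifitm3, which blocks virus entry, rose by 1.69 ± 0.15 (adjusted p = 1.58e-05). Oasl2, a sensor of viral RNA, rose at 1 probe (adjusted p = 0.000163; its other probe, at 1.02, was not called), and Oas2 of the same family rose by 1.44 ± 0.18 (0.000277; at least 2.12-fold). Of 21 genes of reactive astrocytes, 15 were called higher and 0 lower, or 17 adjusted over the list alone, with a median of 1.14 (adjusted p = 3.44e-21; 0.00689 with an estimated correlation). C4b rose by 2.64 ± 0.20 (5.4e-06), the endotoxin receptor gene Cd14 by 2.46 ± 0.27 (0.000103) and the protease inhibitor gene Timp1 by 2.45 ± 0.24 (3.35e-05). Without the 3 arrays with Eif2s3y signal, which leaves only array C of WT saline, the list medians were 0.90 for interferon and 1.16 for reactive astrocyte genes. The number of reactive astrocyte genes called was 8 with the brightness covariate, with a median of 1.09. The array means of the 3 lists put every CX array above every WT array.

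**Figure D1:**
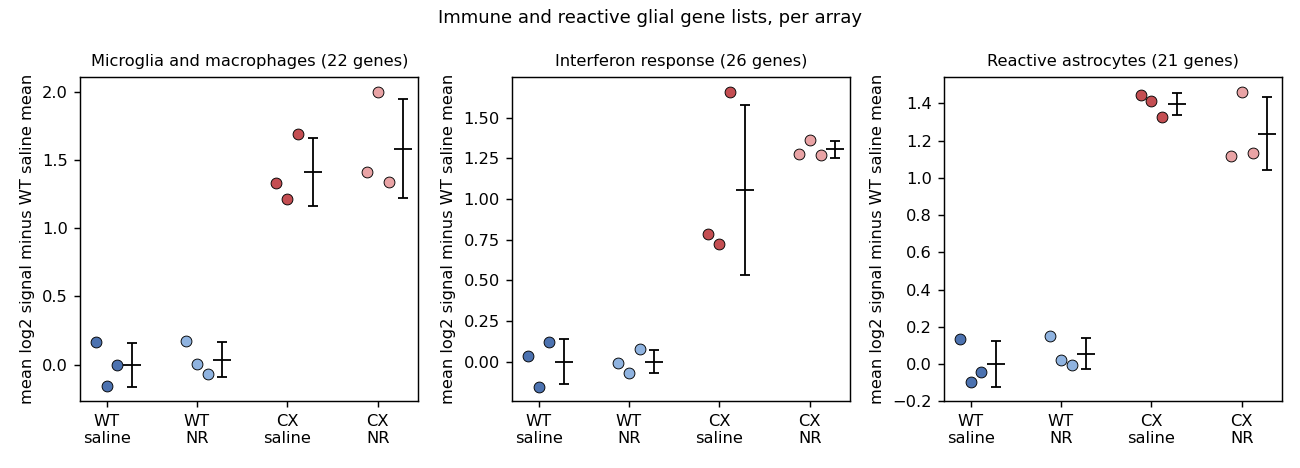
Mean log2 signal of the microglia and macrophage list (22 genes), the interferon response list (26 genes) and the reactive astrocyte list (21 genes) on each of the 12 arrays, as the difference from the WT saline mean. Points are arrays, horizontal bars group means and vertical bars SD (n = 3); every CX array lies above every WT array, and the interferon mean of CX saline array C (1.658) lies above those of arrays A (0.786) and B (0.725).

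Smaller lists moved in CX under saline. Targets of glucocorticoid and FOXO signalling rose (median 0.50, adjusted p = 1.92e-06; 0.496 with an estimated correlation), with 3 of 20 genes called higher, or 8 adjusted over the list alone. Beside Lcn2 these were Txnip, an inhibitor of thioredoxin (1.13 ± 0.28, adjusted p = 0.0486), and Irs2, an adaptor of the insulin receptor (0.80 ± 0.18, 0.0287). Genes of the growth hormone and IGF axis rose (median 0.15, adjusted p = 0.00786; 0.137 with an estimated correlation), with 3 of 17 called, or 4 adjusted over the list alone. These were Socs3, a brake on cytokine signalling (2.27 ± 0.25, 0.000101), the binding protein gene Igfbp7 (1.13 ± 0.23, 0.0164) and Irs2. Cholesterol synthesis genes fell (median -0.45, adjusted p = 1.92e-06; 0.262 with an estimated correlation), with 2 of 18 called lower, or 10 adjusted over the list alone. Msmo1 (-1.04 ± 0.18, adjusted p = 0.00594) and Sc5d (-0.90 ± 0.17, 0.0112), enzymes late in that pathway, were called, and Idi1 (-0.81, 0.0639), an early one, was not. With brightness as a covariate, Msmo1 (adjusted p = 0.146), Sc5d (0.165), Irs2 (0.221), Txnip (0.53) and Igfbp7 (0.168) did not pass. The fit without the arrays with Eif2s3y signal leaves only array C of WT saline. There the log2 fold change was -0.765 for Msmo1, -0.858 for Sc5d, 1.326 for Txnip and 1.255 for Igfbp7. Without CX saline array A, Irs2 (0.113), Txnip (0.193), Igfbp7 (0.0962) and Sc5d (0.0625) did not pass. Without CX saline array B, Irs2 (0.106), Txnip (0.218), Igfbp7 (0.0955) and Sc5d (0.0715) did not pass. Irs2 also lost its call without WT saline array A (0.0501) or C (0.0976), Igfbp7 without WT saline array B (0.0548) or C (0.0541), and Txnip without WT saline array B (0.0964), WT saline array C (0.118), CX NR array A (0.0663) or WT NR array B (0.0637). The growth hormone and IGF list did not pass without WT saline array B (adjusted p = 0.0891) or without the arrays with Eif2s3y signal (0.276).

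Some brainstem, red cell and mitochondrial genes fell in CX under saline. Brainstem and deep nuclear genes had a median of -0.78 (adjusted p = 0.00118; 0.549 with an estimated correlation), with 2 of 19 called lower, or 3 adjusted over the list alone. Tph2 (-3.13 ± 0.72, adjusted p = 0.0333) and Nefh, a neurofilament of large axons (-0.92 ± 0.18, 0.0117), fell. Tph2 was at 10.75 and 9.42 on WT saline arrays A and C, but at 7.33 on array B. The WT NR arrays had 6.13, 7.74 and 5.25, and the CX saline arrays 5.34, 5.48 and 7.30. The Tph2 difference thus rested mainly on these WT saline arrays and cannot be read as an effect of genotype alone. Slc6a4, the serotonin transporter, was not called (adjusted p = 0.0542). Gpc5 (-1.60 ± 0.21, 0.000611), the troponin gene Tnnt1 (-2.02 ± 0.46, 0.0335) and Slc17a8, a vesicular glutamate transporter of serotonin and cholinergic neurons (-1.44 ± 0.33, 0.0324), fell as well. The red cell genes Hbb-bt (-1.70 ± 0.35, 0.018) and Alas2, which starts haem synthesis (-1.35 ± 0.32, 0.0413), fell. Oxidative phosphorylation genes had a median of -0.07 (adjusted p = 0.0276; 0.689 with an estimated correlation), with 2 of 68 called lower, Cox6c (-0.78 ± 0.19, 0.0473) and Ndufb5 (-0.58 ± 0.14, 0.0486), or 5 adjusted over the list alone; Atp5a1 was not called (-0.54, 0.0605). Without CX saline array A, none of Tph2, Tnnt1, Slc17a8, Hbb-bt, Alas2, Nefh, Cox6c and Ndufb5 passed (adjusted p from 0.0778 for Nefh to 0.166 for Alas2). Without CX saline array B, Tph2, Tnnt1, Slc17a8, Hbb-bt, Alas2, Cox6c and Ndufb5 did not pass (from 0.1 for Hbb-bt to 0.198 for Alas2). Without WT saline array A, the same 7 did not pass (from 0.0717 for Hbb-bt to 0.169 for Ndufb5). Without WT saline array C, Tph2 (0.0833), Slc17a8 (0.0824), Hbb-bt (0.0694), Alas2 (0.126), Cox6c (0.126) and Ndufb5 (0.118) did not pass. Cox6c, Ndufb5 and Alas2 also ended without CX NR array A, CX NR array C or WT NR array B (from 0.0526 for Cox6c to 0.0717 for Ndufb5), and the first 2 without CX NR array B (both 0.0614) or CX saline array C (0.0748 and 0.0628). The median of 19 oligodendrocyte and myelin genes was -0.27 (adjusted p = 0.0284; 0.689 with an estimated correlation), with 1 called, Apod, which was higher; Mal (-0.50), Car2 (-0.62) and Qdpr (-0.62) were not called, and without the arrays with Eif2s3y signal the list did not pass (0.698; median -0.07). Without those arrays the median of the brainstem list was 0.15 in place of -0.78, and that list (0.596) and the oxidative phosphorylation list (0.0648) did not pass. With z-scores and with series matrix values, the lists of oxidative phosphorylation (0.26) and oligodendrocytes (0.0638) did not pass either. The oxidative phosphorylation list also ended without CX saline array B (0.256) or C (0.105), and the oligodendrocyte list without CX saline array A (0.255), CX saline array B (0.246) or WT saline array B (0.59). With brightness as a covariate, none of the 8 genes named above as lost without CX saline array A passed (adjusted p from 0.251 for Nefh to 0.598 for Cox6c). Without the arrays with Eif2s3y signal, which leaves only array C of WT saline, Tph2, Tnnt1, Alas2, Nefh, Cox6c and Ndufb5 did not pass. The log2 fold change there was -3.38 for Tph2, -1.825 for Alas2, -0.99 for Cox6c and -0.66 for Ndufb5, larger in size than with all arrays. For Tnnt1 (-1.41) and Nefh (-0.57) it was smaller.

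The transcripts of genes of the study's question did not move as lists in CX under saline. Transcript levels do not measure PARP1 activation, NAD+, SIRT1 activity or the clearance of mitochondria, so those were not tested here. Nucleotide excision repair (21 genes measured, adjusted p = 0.793), p53 targets (20, 0.251), PARPs and base excision repair (18, 0.716), NAD metabolism (11, 0.238), sirtuins and mitochondrial biogenesis (19, 0.988) and mitophagy and mitochondrial dynamics (21, 0.406) were tested with camera. Among their members, 1 gene was called: Naprt, which makes NAD+ from nicotinic acid (0.73 ± 0.17, adjusted p = 0.0358; its other 2 probes, at 0.51 and 0.67, were not called). That call ended without any 1 of CX saline array A (0.112), B (0.109) or C (0.0627) and WT saline array B (0.064) or C (0.118), and with brightness as a covariate (0.114). Values without a call were 0.06 for Parp1 (adjusted p = 0.878), -0.35 for Sirt1 (0.257), -0.03 for the mitochondrial biogenesis regulator Ppargc1a (0.951), -0.45 for the NAD+ salvage enzyme Nampt (0.281), -0.32 for the NR kinase Nmrk1 (0.459) and 0.26 for the mitophagy kinase Pink1 (0.4). Among p53 targets, the death receptor gene Fas (1.19, 0.0639) and the cell cycle inhibitor gene Cdkn1a (0.99, 0.122) were not called. In the repair lists, Ddb2 (0.65, 0.0939), Pold1 (0.44, 0.116), Apex1 (0.44; another probe -0.08) and Aptx (-0.47) were not called. Pnp (0.36), Foxo1 (0.77, 0.0604), Gabpa (-0.84; another probe -0.06), Tax1bp1 (-0.77, 0.0841) and Vdac1 (-0.40) were not called either.

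The same genotype difference was measured in mice given NR, from arrays that the saline comparison does not use. The immune and glial rise was present here too: Fcgr2b, an inhibitory antibody receptor, the attracting cytokine Ccl4 and the leukocyte antigen Cd52 rose in CX. Genes of red cells fell, among them Slc4a1, the anion exchanger of the red cell membrane, Hba-a1, a haemoglobin chain, and Alas2. Of 15725 probes, 482 were called: 304 higher in CX (246 genes) and 178 lower (165 genes). Ccl21a rose by 3.44 ± 0.46 (adjusted p = 0.000385) and Ccl21c by 3.10 ± 0.34 (8.92e-05; at least 6.41-fold), again uncertain as separate genes. Ccl4 rose by 3.31 ± 0.30 (1.48e-05; at least 7.49-fold; its other probe, at 0.77, was not called), Fcgr2b by 3.11 ± 0.22 (2.93e-06) and Cd52 by 3.04 ± 0.29 (2.22e-05). Alas2 (-2.09 ± 0.32, 0.00139), Slc4a1 (-1.94 ± 0.25, 0.000287), Hba-a1 (-1.78 ± 0.25, 0.000578), Hbb-bt (-1.70 ± 0.35, 0.0136) and the peptide transporter gene Slc15a2 (-1.52 ± 0.37, 0.0348) fell. Without CX NR array C, Hbb-bt (0.0787) and Slc15a2 (0.13) did not pass, and Slc15a2 also ended without CX NR array A (0.098), CX NR array B (0.0547), WT NR array B (0.0938) or WT NR array C (0.0754), and with brightness as a covariate (0.195). The count was 195 without CX NR array B, 231 without CX NR array C, 212 without WT NR array A, 229 without WT NR array B and 1054 without WT NR array C. It was 867 with array weights, 55 with brightness as a covariate, 227 without the arrays with Eif2s3y signal and 313 with that signal as a covariate. No focus gene was called: Parp1 had -0.13 (adjusted p = 0.698), Sirt1 0.17 (0.615), Ppargc1a 0.15 (0.69), Nampt -0.16 (0.747), Nmrk1 -0.05 (0.934) and Pink1 -0.17 (0.616).

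As lists, under NR, 17 of 22 microglia genes were called higher and 0 lower (18 adjusted over the list alone; median 1.82, adjusted p = 1.55e-26; 0.0612 with an estimated correlation). Of the interferon genes, 16 of 26 were higher (23 adjusted over the list alone; median 1.28, 1.72e-26; 0.0651 with an estimated correlation). Of the reactive astrocyte genes, 10 of 21 were higher (15 adjusted over the list alone, with 1 lower; median 0.99, 2.18e-15; 0.0207 with an estimated correlation). With brightness as a covariate, 10 microglia, 4 interferon and 4 reactive astrocyte genes were called higher, with medians of 1.70, 0.95 and 0.92. Autophagy and lysosome genes rose (median 0.09, 0.00608; 0.0612 with an estimated correlation), with 2 of 31 called, the lysosomal protease gene Ctss and the granulin gene Grn, or 7 adjusted over the list alone; Ctss is also in the microglia list. Antioxidant genes rose (median 0.18, 0.00608; 0.218 with an estimated correlation), with 2 called, Hmox1, which breaks down haem, and the metallothionein gene Mt3. Oligodendrocyte genes rose (median 0.39, 0.000362; 0.512 with an estimated correlation), with 2 of 19 called, or 3 adjusted over the list alone. Ribosomal protein genes rose by a median of 0.12 (0.00297; 0.512 with an estimated correlation), but with z-scores camera gave the other direction, without a call (0.186). Blood genes fell, with 4 of 6 called lower (median -1.74, 0.000111; 0.0612 with an estimated correlation). Endothelial and pericyte genes fell (median -0.29, 0.00739; 0.299 with an estimated correlation), with 4 of 21 called lower, or 5 adjusted over the list alone, among them the smooth muscle actin gene Acta2 and the channel gene Kcnj8. Lists of Purkinje cells (median -0.37, 0.00219; 0.5 with an estimated correlation), granule cells (-0.24, 0.00458; 0.512) and meninges (-0.28, 0.0403; 0.512) fell with 1 call each. Their calls, like that of the oligodendrocyte list, depended on the setting: with brightness as a covariate the adjusted p was 0.433 for Purkinje cells, 0.39 for granule cells and 0.273 for oligodendrocytes. With z-scores and with series matrix values, the lists of antioxidant genes (0.172), autophagy and lysosome (0.0673), oligodendrocytes (0.0673) and meninges (0.0698) did not pass. The meninges list ended without CX NR array A (0.0995), WT NR array A (0.213) or WT NR array C (0.095), the granule cell list without CX NR array B (0.0578) or WT NR array C (0.117), the endothelial list without CX NR array A (0.0591) and the ribosomal list without WT NR array B (0.0778). The endothelial list also ended with the strict detection filter (0.108). The ribosomal list also ended with array medians set equal (0.435) and with brightness as a covariate (0.0566). The 6 study lists were not called, at 0.165 for nucleotide excision repair, 0.335 for p53 targets, 0.699 for PARPs and base excision repair, 0.988 for NAD metabolism, 0.76 for sirtuins and 0.472 for mitophagy.

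The overlap of the genotype comparisons differed by direction. Of the probes called, 133 were higher in CX under both treatments, where independent lists of these sizes would share 4.58, and 6 were lower under both, against 0.962. The 6 were Alas2, Ercc8, Hba-a1, Hbb-bt, Pgap4 and Xpa. Of the 237 probes higher under saline, 208 (87.8%) had the same sign under NR, and their median log2 fold change was 1.15 under saline and 0.93 under NR. Of the 85 lower under saline, 21 (24.7%) had the same sign, with medians of -0.86 and 0.16. Over all 15725 probes, the log2 fold changes of the comparisons correlated at r = 0.0925 (Spearman rho = -0.232), outside simulated data without effects (r from -0.022 to 0.035, rho from -0.018 to 0.022), in which probes vary independently, but within the residual regroupings (95% of r between -0.45 and 0.54). That r was -0.0189 with the strict detection filter. It is a correlation across genes, which are not independent replicates.

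**Figure D2:**
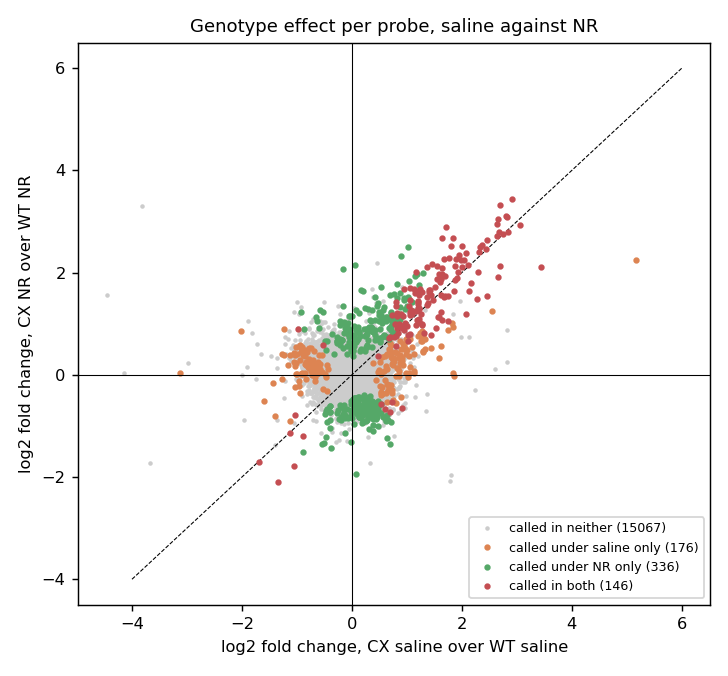
Log2 fold change of each of 15725 probes, CX saline over WT saline (x axis) against CX NR over WT NR (y axis). Colours mark probes called in both comparisons (of either sign), under saline only, under NR only or in neither; the probes called higher in both follow the diagonal, and most of those called lower under saline do not.

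The effect of NR in CX mice was read from CX NR against CX saline, the contrast closest to the study's question of treatment. With limma, 0 of 15725 probes were called; 2189 had an unadjusted p under 0.05, against 786 by chance, and the lowest adjusted p was 0.158. Among the genes taken by the rule, the pituitary hormone gene Prl had the largest value, 4.98 ± 1.06 (adjusted p = 0.158). Prl was at 9.86 to 10.06 on CX NR and at 4.85 to 5.10 on CX saline arrays. The hormone gene Gh moved with it, at 6.90 to 7.42 and 4.58 to 5.26. The source of these hormone transcripts was not tested. The rule also took Cbln4, a synapse organiser (1.32), and Il33, an alarm cytokine of glia (1.27). Zmat4 had 0.98, Sec11c 0.81 and Apbb1ip 0.77, all at an adjusted p of 0.158. The lower values at the same adjusted p were -1.39 for Golga2 (its other 4 probes lay between -0.13 and -0.26), -1.04 for A3galt2, -0.75 for Rfx1, -0.73 for Gdpd5, -0.72 for the DNA polymerase gene Pold1 and -0.65 for St3gal3. None of these passed. Array weights gave 906 calls, the fit of only the compared arrays 3, and the fit without the arrays with Eif2s3y signal 2. Without CX saline array C, 256 probes were called, and without WT saline array C, 1.

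Some lists differed with NR in CX by camera, none of them with an estimated correlation. Glucocorticoid and FOXO targets were lower (median -0.39, adjusted p = 8.02e-05; 0.473 with an estimated correlation), with 6 of 20 genes lower adjusted over the list alone. Plin4, a lipid droplet coat gene, had -1.49 (0.158), Irs2 -0.86 (0.158) and Lcn2 -3.06 ± 0.86 (0.18). The Lcn2 difference rested on CX saline arrays A (11.84) and B (11.43). Array C stood at 6.77, within the CX NR values of 6.54 to 7.56. Oligodendrocyte genes were higher (median 0.38, 8.58e-05; 0.482 with an estimated correlation), with 7 of 19 higher and 1 lower adjusted over the list alone; Opalin had 1.22 (0.177), Tspan2 0.62 and Cryab 0.59. Endothelial and pericyte genes were lower (median -0.45, 0.000553; 0.456 with an estimated correlation), with 4 of 21 lower adjusted over the list alone; Acta2 had -1.09 (0.171), Vwf -1.18 (0.203) and Esam -0.63. Brainstem genes were higher (median 0.63, 0.0252; 0.598 with an estimated correlation), with Slc5a7 at 1.39, Hoxa2 at 0.72 and Nefh at 0.66. Interferon genes were higher (median 0.20, 0.0318; 0.646 with an estimated correlation), with Gbp3 at 0.97, Ifit2 at 0.69 and Lgals3bp at 0.63. Clock genes were lower (median -0.20, 0.0399; 0.456 with an estimated correlation), with Per1 at -0.43, Csnk1e at -0.54 and Tef at -0.55. With brightness as a covariate, the lists of oligodendrocytes (0.0646), brainstem (0.502), interferon (0.806) and clock genes (0.447) did not pass. The brainstem list also ended without CX saline array A (0.184) or B (0.143), the interferon list without CX NR array B (0.0735), CX saline array A (0.255) or CX saline array B (0.488), and the clock list without CX NR array B (0.275) or CX saline array B (0.217).

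The 6 study lists were not called with NR in CX. The adjusted p was 0.36 for nucleotide excision repair, 0.508 for p53 targets, 0.799 for PARPs and base excision repair, 0.799 for NAD metabolism, 0.694 for sirtuins and mitochondrial biogenesis and 0.2 for mitophagy. Fundc1, a mitophagy receptor gene, had 0.58 (adjusted p = 0.165) and Rhot2, which anchors mitochondria to motors, -0.39. The respiratory gene regulator Nrf1 had -0.57, and the energy sensor gene Prkaa2 -0.61, with 0.07 at its other probe. Slc12a8, described as a transporter of NAD+ precursors, had -0.41, Nnmt -0.36, Parp2 -0.23, Smug1 0.36, Rpa3 0.44, Bbc3 -0.99 (another probe 0.01) and Ccng1 0.74. Among the focus genes, Sirt1 had 0.26 (0.492), Parp1 0.18 (0.726), Ppargc1a 0.13 (0.768), Nampt 0.33 (0.504), Nmrk1 0.32 (0.523) and Pink1 -0.14 (0.724). None of these values was called.

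Whether NR moved the CX profile back toward that of WT was examined across probes. Between the genotype effect under saline and the NR effect in CX, r was -0.609. Both comparisons use the CX saline arrays with opposite sign, and simulated data without any effect gave -0.5 (range -0.52 to -0.47). The covariance was -0.062 against -0.019 simulated. Regroupings of the residuals gave r between -0.76 and -0.14 (95%), which holds the observed r, and a covariance between -0.052 and -0.0054, which does not hold the observed covariance. Whether that excess reflects NR or the CX saline arrays that both comparisons share was not tested.

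In wild-type mice, NR was compared with saline to see its effect without the repair defect. With limma, 0 of 15725 probes were called; 2022 had an unadjusted p under 0.05, against 786 by chance, and the lowest adjusted p was 0.279. At that adjusted p, Rabif had 1.24, Slc4a1 1.22, the procollagen protease gene Bmp1 0.89 (its other 3 probes lay between 0.24 and 0.28), Akap8l 0.79, Atad3a 0.67 and Ogfr 0.63. On the lower side were Dgkk (-1.65), the synaptic pentraxin gene Nptx2 (-1.25), Lbh (-1.13), Dsn1 (-0.94), Rhob (-0.83) and Clip4 (-0.63). The choroid plexus list was the only one called, and it was higher with NR (14 genes, median 0.80, adjusted p = 0.00103; 0.771 with an estimated correlation), with Aqp1 at 1.47, Folr1 at 1.10 and Clic6 at 0.97. On WT saline array B, Ttr, an abundant choroid plexus transcript, stood at 10.55, against 14.52 and 14.68 on the other WT saline arrays, and the mean of the list at -1.5 from the WT saline mean, against 0.584 and 0.916. Without the 3 arrays with Eif2s3y signal, which include that one, the list did not pass and camera gave the other direction (adjusted p = 0.569). It did not pass without WT saline array B alone (0.816) or without WT NR array C (0.0909). Without WT NR array C 49 probes were called, without WT saline array A 1, without WT saline array B 6 and without WT saline array C 2. With array medians set equal, the median of all probes lay at -0.114.

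The study lists were not called with NR in WT, at an adjusted p of 0.224 for nucleotide excision repair, 0.886 for p53 targets, 0.502 for PARPs and base excision repair, 0.191 for NAD metabolism, 0.972 for sirtuins and 0.608 for mitophagy. Ddb2, which senses damage in chromatin, had 0.73 (adjusted p = 0.279), Pold1 0.58 (0.279) and the glycosylase gene Nthl1 0.56 (0.3). Parp2 had 0.31, Nnmt 0.37, Naprt 0.31 (another probe -0.10), Polrmt 0.40 and Prkaa2 -0.53. Tax1bp1 had -0.75, Vdac1 -0.34, Zmat3 -0.65 and Gadd45a -0.59. Sirt1 had -0.27 (0.481), Parp1 0.20 (0.442), Ppargc1a -0.05 (0.92), Nampt -0.08 (0.851), Nmrk1 0.06 (0.932) and Pink1 0.29 (0.444). None was called.

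The interaction asked whether the NR effect differed between genotypes. The test called 418 of 15725 probes, 190 with a higher NR effect in CX and 228 with a lower one; 3579 had an unadjusted p under 0.05, and the lowest adjusted p was 0.0208. In all 418, NR had opposite signs in CX and WT. The selection favours this, because the interaction picks large differences between NR effects and neither NR comparison called a probe. The share of opposite signs over all probes was not counted. Of them, 62 were also called between genotypes under saline, 137 under NR and 226 under neither. Among the called probes, Prl had the largest difference, 7.11 (adjusted p = 0.0323), with 10.90, 10.56 and 4.96 on the WT saline arrays (Gh: 11.37, 12.12 and 4.50). Its difference was 3.22 without the arrays with Eif2s3y signal (adjusted p = 0.18) and 3.51 with brightness as a covariate (0.999), which ended its call. Prl was followed by Gm14325 (2.94 ± 0.74, 0.0478; another probe, at 0.33, was not called), Tnnt1 (2.87 ± 0.66, 0.0381), Dgkk (2.28 ± 0.49, 0.0334) and 2610301B20Rik (2.24 ± 0.44, 0.0301). On the lower side stood the actin gene Actb (-3.87 ± 0.88, 0.0379), the formyl peptide receptor gene Fpr2 (-2.05 ± 0.48, 0.0394), the repair glycosylase gene Mpg (-2.03 ± 0.50, 0.0434; another probe, at -0.95, was not called), Slc4a1 (-2.02 ± 0.35, 0.0248) and Fam117a (-1.86 ± 0.38, 0.0323). Of the other Actb probes, 1 had -3.77 and was called, and the 3 brighter ones had -0.53, -0.28 and -0.08 and were not. The focus genes were not called, with 0.53 for Sirt1 (0.177), 0.22 for Nampt (0.581), 0.27 for Nmrk1 (0.64), 0.18 for Ppargc1a (0.688), -0.19 for Parp1 (0.63) and -0.42 for Pink1 (0.258).

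The number of these interaction calls depended on which arrays and settings were used. Without CX NR array B, CX NR array C, CX saline array A, CX saline array B or WT NR array A, limma called 0 probes, with 2542 to 2918 at an unadjusted p under 0.05. The count was 19 without WT NR array B, 142 without WT saline array A, 201 without WT saline array C, 705 without CX NR array A, 972 without CX saline array C and 1337 without WT NR array C. It was also 0 without a variance trend, with brightness as a covariate and without the arrays with Eif2s3y signal (unadjusted p under 0.05 for 3469, 589 and 2311 probes). Other settings gave 148 calls (no detection filter), 763 (Eif2s3y signal as a covariate) and 1507 (array weights). With array medians set equal, 558 probes were called, of which 79.4% were higher, against 45.5% in the quantile-normalized data, and the median of all probes lay at 0.153. With brightness as a covariate, the difference was 0.88 for Dgkk, 1.61 for Tnnt1, -1.90 for Actb, 1.51 for Gm14325, -1.115 for Fam117a, -1.504 for Fpr2, -1.649 for Mpg, 2.018 for 2610301B20Rik and -2.704 for Slc4a1, each at an adjusted p of 0.999. None of the 10 genes above kept its call in every leave-one-out fit. In the fits that ended these calls, the difference ran from -1.977 to -2.162 for Slc4a1 and from -1.617 to -1.841 for Fam117a. It ran from 6.061 to 7.162 for Prl and from -1.653 to -2.481 for Mpg. Prl did not pass without CX NR array B (0.0913) or C (0.101), CX saline array A (0.0821) or B (0.0973), WT NR array A (0.107) or B (0.0664) or WT saline array A (0.0524). Without WT NR array B, 2 of the 10, Slc4a1 and 2610301B20Rik, passed, and without WT saline array A, Slc4a1 and Fam117a passed. Fpr2 (0.0655), Actb (0.0617) and Gm14325 (0.077) also ended without WT saline array C, and Mpg without CX NR array A (0.0593). The median raw signal followed the same pattern, higher with NR in CX (102 against 86.8) and lower with NR in WT (83.6 against 99.9).

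Lists also differed in their NR effect between genotypes. Oligodendrocyte genes (median difference 0.67, adjusted p = 0.000448; 0.585 with an estimated correlation) and brainstem genes (1.37, 0.0122; 0.585) had a higher NR effect in CX, with 2 and 1 genes called, or 6 and 4 adjusted over the list alone. Endothelial and pericyte genes (-0.49, 0.0065), blood genes (-1.38, 0.0434), glucocorticoid and FOXO targets (-0.42, 0.0434) and granule cell genes (-0.41, 0.0488) had a lower one, each at 0.585 with an estimated correlation. Adjusted over the list alone, 5 endothelial genes and 1 gene of each of the other 3 lists were lower. With brightness as a covariate, the lists of oligodendrocytes (0.318), brainstem (0.597), glucocorticoid targets (0.988) and granule cells (0.988) did not pass. Without the arrays with Eif2s3y signal, only the endothelial list of these 6 passed (0.00233). The oligodendrocyte and endothelial lists passed in all 12 leave-one-out fits, but the endothelial list did not pass with the strict detection filter (0.0758). The brainstem list ended without CX saline array A (0.0764) or WT NR array C (0.0715). The blood list ended without CX NR array A (0.124), CX NR array C (0.0511), CX saline array A (0.0764), WT NR array C (0.231) or WT saline array B (0.115). The glucocorticoid list passed in 4 of the 12 fits and the granule cell list in 5, with values up to 0.185 (without CX saline array B) and 0.231 (without WT NR array C). The immune lists did not differ: the adjusted p was 0.206 for interferon, 0.437 for microglia and 0.518 for reactive astrocytes, so their rise in CX was not shown to change with NR. Across all probes, the NR effects in CX and WT correlated at r = -0.489 (Spearman rho = -0.507), outside simulated data without effects (r from -0.032 to 0.037) but within the residual regroupings (95% of r between -0.53 and 0.51).

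**Figure D3:**
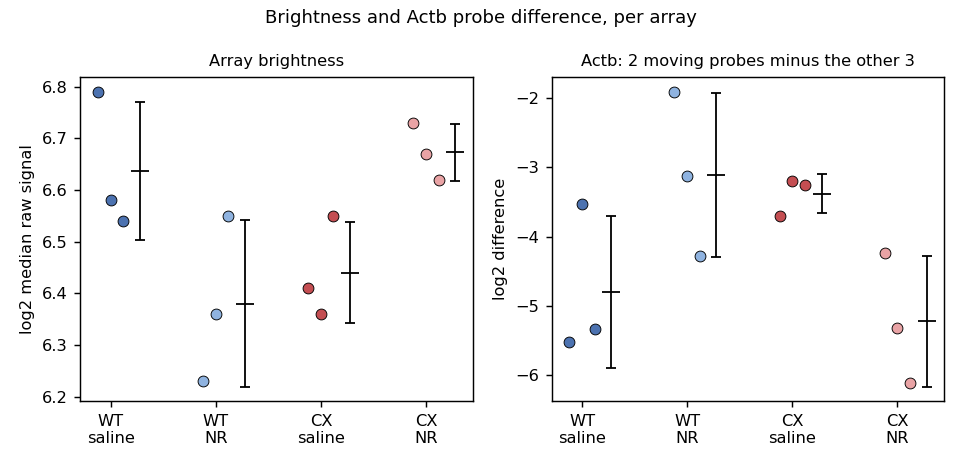
Log2 median raw signal of each of the 12 arrays (left) and log2 difference between the 2 Actb probes that moved in the interaction and the other 3 (right). Points are arrays, horizontal bars group means and vertical bars SD (n = 3); the medians of CX NR lie above those of CX saline, and most of WT NR lie below WT saline, with the reverse order for Actb.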

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

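The tests of array brightness and of red and white blood cells on the immune genes, the test of sex and the test of genes next to Xpa were chosen after the results were seen. A test of the difference between genotypes (the interaction) singled out the results in the next paragraph; what lies behind the difference is weighed after them.

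The interaction called 418 probes. The log2 differences of the named genes (NR effect in CX minus that in WT) were 7.11 for Prl, 2.94 for Gm14325, 2.87 for Tnnt1, 2.28 for Dgkk, 2.24 for 2610301B20Rik, 2.13 for Cbln4, 1.89 for Il33, 1.86 for Zmat4, 1.84 for Nptx2, 1.78 for Lbh, 1.48 for Gbp3 and 1.43 for Ifit2. They were 1.37 for Nefh, 1.34 for Sec11c, 1.33 for Dsn1, 1.31 for Cox6c, 1.29 for Tax1bp1, 1.22 for Msmo1, 1.15 for Rhob, 1.11 for Tspan2, Zmat3 and Clip4, 0.96 for Mal and 0.89 for Fundc1. Lower differences were -3.87 for Actb, -2.05 for Fpr2, -2.03 for Mpg, -2.02 for Slc4a1, -1.86 for Fam117a, -1.56 for Bmp1, -1.55 for A3galt2, -1.42 for Akap8l, -1.34 for Irs2 and Bbc3 and -1.29 for Pold1. Further ones were -1.24 for Gdpd5, -1.11 for St3gal3, -1.10 for Rfx1, -1 for Nrf1, -0.95 for Atad3a, -0.84 for Ogfr and -0.68 for Polrmt. Among lists, camera gave an adjusted p of 0.000448 for oligodendrocytes and myelin, 0.0065 for endothelial cells and pericytes, 0.0122 for brainstem and deep nuclei, 0.0434 for blood, 0.0434 for glucocorticoid and FOXO targets and 0.0488 for granule cells. With an estimated correlation, the adjusted p of each of these 6 lists was 0.585.

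The first pattern is the set of interaction calls. Of 100 drawn regroupings of treatment within genotype, only the real one (1 of 100) called as many as 418 probes, a share under 0.05, although another called 398. The regroupings cannot separate a response to NR from array quality or brightness that differs between the groups. Within groups, 93.3% of 416 probes followed the difference between moving and steady Actb probes in the predicted direction, just above the shuffles (9.11 to 92.6). The moving Actb probes were themselves interaction calls, and no measure of RNA quality was at hand to tie their difference to quality. That difference also ran with array brightness over the 12 arrays (r = -0.777). RNA or labelling quality therefore stays open, as the test cannot single it out. For array brightness the share was 90.9% of 418 probes, inside the shuffles (6.06 to 94.4), and with brightness as a covariate the median size went from 1.01 to 0.69 and the median standard error from 0.22 to 0.35, so brightness stays open. A response to NR that differs by genotype also stays open, as untested apart from these.

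The second pattern is the rise of immune and reactive glial genes in CX, over the 39 called members of 3 lists. Sex of the animals is argued against as the whole cause: without the 3 arrays with Eif2s3y signal, the median log2 fold change under NR was 1.94, against 1.89 with all arrays. Array brightness is argued against likewise, since with it as a covariate the median under saline was 1.84, against 1.69. Whole blood left in the tissue is argued against by 4 red cell transcripts (median -1.2 under saline, 3 called lower, 0 called higher, Slc4a1 at 0.08). This holds only if red cells carry as much of this RNA in CX as in WT, which was not tested. White blood cells stay open. Their 2 measured transcripts, S100a8 (2.82) and S100a9 (2.61), had a median of 2.72 under saline and 0.18 under NR, with 0 called. RNA or labelling quality and alleles linked to Xpa were not tested for this pattern, so an effect of the missing repair genes is 1 of several hypotheses that remain.

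The third pattern is a cluster of calls next to Xpa. Of 100 measured genes next to it, 5% were called in both genotype comparisons (Ccl21b, Ccl21a, Rusc2, Tesk1 and Pgap4), against 1.01% of 10525 other genes (Fisher's exact p = 0.0039), and 97.4% of 8464 equally large windows held fewer. Alleles of another strain linked to the targeted locus could produce this, but the share did not exceed the bound set for the windows. Without the near-identical Ccl21 genes the share was 3.06% of 98 genes (Fisher's exact p = 0.0778), above 94.1% of windows, so neither explanation was excluded. Next to Ercc8, 0 of 81 genes were called in both. A regulatory effect of losing Xpa was not tested.

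Other splits of the arrays were counted for the group comparisons. With 3 arrays against 3, the 10 splits are too few for a share under 0.05. Under saline the real split called 322 probes and the highest other 102, with 1 of 10 splits as high. Under NR the real split called 482 and the highest other 3, with 1 of 10 as high. For NR in CX, limma called 0 probes in the real split (2189 at an unadjusted p under 0.05) and at most 0 in others, so 10 of 10 were as high. For NR in WT it called 0 (2022 at an unadjusted p under 0.05) and another split called 104, so 10 of 10 were as high.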

How the results depend on the processing

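The brightness and Eif2s3y settings were chosen after the data were seen. Of the called probes, 0 changed sign under the other settings that tested them. Of the named calls, 20 of 33 under saline, 9 of 12 under NR and 0 of 10 in the interaction passed in all leave-one-out fits, and 17, 9 and 0 in all other settings. Under saline, the count of called probes was 322, and 943 with median normalization, 203 with the strict filter, 207 with only the arrays compared, 822 with array weights, 113 with the brightness covariate, 98 without the 3 arrays with Eif2s3y signal, and 159 to 613 in leave-one-out fits. Under NR it was 482, and 867 with array weights, 737 with series matrix values and the replicate block (587 with those values alone), 55 with the brightness covariate, 227 without the Eif2s3y arrays, 313 with Eif2s3y as a covariate, and 195 (without CX NR array B) to 1054 (without WT NR array C). NR in CX gave 0 with limma (2189 at an unadjusted p under 0.05), 3 with only the arrays compared, 906 with array weights, 2 without the Eif2s3y arrays, and 0 to 256 in leave-one-out fits; NR in WT gave 0 (2022 at an unadjusted p under 0.05) and 0 to 49. The interaction gave 418, and 148 without a detection filter, 1507 with array weights, 0 without a variance trend, 686 with series matrix values and the replicate block (397 with those values alone), 0 with the brightness covariate, 0 without the Eif2s3y arrays (3469, 589 and 2311 at an unadjusted p under 0.05 for these 3), 763 with the Eif2s3y covariate, and 0 to 1337 in leave-one-out fits. The correlation of genotype effects (0.0925) was 0.0208 with z-scores and with series matrix values, -0.0189 with the strict filter, 0.174 without the Eif2s3y arrays, and 0.0219 to 0.19 in leave-one-out fits. That of NR effects (-0.489) was -0.545 with z-scores and with series matrix values, -0.579 with the strict filter, -0.226 without the Eif2s3y arrays, and -0.548 to -0.371. That of reversal (-0.609) was -0.56 with the brightness covariate, -0.49 without the Eif2s3y arrays, and -0.706 to -0.546. The number of called lists, 34, was 22 with the strict filter, 2 with an estimated correlation, 17 with fry, and 28 to 49 in leave-one-out fits. With z-scores, with series matrix values, and with those and the replicate block, camera's direction turned for these lists: ribosomal proteins in genotype under NR (adjusted p = 0.186, 0.186 and 0.174), in NR in CX (0.0159, 0.0159 and 0.00941) and in the interaction (0.0156, 0.0156 and 0.0143), and oxidative phosphorylation in NR in CX (0.0254, 0.0254 and 0.021) and in the interaction (0.0433, 0.0433 and 0.029). The interferon list in NR in WT turned with the brightness covariate (0.0438). Without the Eif2s3y arrays, oligodendrocytes under saline (0.698) and the choroid plexus in NR in WT (0.569) and in the interaction (0.0149) turned. The cause was not tested. Whether the replicate numbers pair the samples was not settled. Over 18 same-numbered pairs, r ran from -0.22 to 0.28 (mean 0.037, against -0.018 for other pairs), and 6 were over 0.1. Of 12 samples, 6 correlated best with their own number. Adding the replicate block to the series matrix values raised the calls from 296 to 308 under saline, from 587 to 737 under NR and from 397 to 686 in the interaction. A slide block was not run because the files used here give no slide. Signal over background limits what is seen: 15725 of 25697 probes passed the detection filter.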

Other observations

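The genes of this part were chosen after their values were seen. Outside the lists, further immune genes were called higher in CX in both genotype comparisons. Ctse, an endosomal protease of antigen-presenting cells, rose by 2.33 under saline and 2.51 under NR, and Ifi27l2a, induced by interferon, by 2.76 and 2.76. The microglial receptor gene Fcrls rose by 2.12 and 2.16. The attracting cytokine gene Cxcl16 rose by 1.68 and 1.52, and the T cell attractant gene Ccl5 by 1.63 and 1.91. Casp1, which matures interleukin 1, rose by 0.89 and 1.18, and Casp8, an initiator of cell death, by 0.69 and 0.74. Icam1, an adhesion molecule of activated vessels, rose by 1.64 and 1.07, the lipid carrier gene Apoe by 0.80 and 0.57, and the mono-ADP-ribosyl transferase gene Parp14 by 1.56 and 1.14.

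Single arrays stood apart in some genes, given here as values without an explanation. The acute phase gene Saa3 was at 7.35, 7.16 and 5.37 on CX saline arrays A, B and C, in the order that Lcn2 took (11.84, 11.43 and 6.77). The chemokine receptor gene Cx3cr1 was at 7.96, 7.96 and 9.71 on the same arrays, and Ccl3 at 5.30, 5.05 and 7.09. Tph2 was at 10.75, 7.33 and 9.42 on the WT saline arrays, and Slc6a4 at 8.18, 5.55 and 7.11. The hormone gene Gh was at 11.37, 12.12 and 4.50 on the WT saline arrays. Pomc was at 8.63 on WT saline array B and at or under 5.40 on the other 11 arrays. The 3 probes of Nnt, a mitochondrial transhydrogenase, were detected on 0 arrays.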
